A study of Homo sapiens with 16 samples.

How the data were processed

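MCF7 is an estrogen receptor positive luminal breast cancer line, and SKBR3 is a breast cancer line with amplified ERBB2, the gene of the HER2 receptor. RNA was measured in 16 libraries in 4 groups of 4, namely control and SPDEF knockdown libraries of each line. SPDEF is an ETS family transcription factor of secretory and luminal epithelium. Per the labels, the knockdown lines were stable lines made with lentiviruses that carried 3 individual short hairpin RNAs. The libraries are not labelled by hairpin, and the controls are called wild type, so it is not stated whether they carried a control hairpin. Per the labels' protocols, RNA was extracted with Trizol and mRNA libraries were sequenced as paired ends with reads of 101 bases. The groups and the replicate numbers came from the sample titles. No label says whether the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

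The deposited values were whole-number counts per gene, 1 column per library, not normalized. Per the submitters' processing notes, the tools named were FastQC, Salmon 1.9 and DESeq2 3.16 with the hg38 genome; their settings, the annotation release and how estimated counts became whole numbers are not given in the sources used here. The deposited counts covered 17426 Ensembl gene IDs. Each of these genes had at least 10 counts in at least 4 libraries, so a gene outside this set was not analysed here. Symbols were taken from a table of gene names, which matched 17314 IDs and left 112 without a symbol. In all, 52 IDs shared a symbol with another ID. Coordinates and gene types were those of GENCODE release 29 on GRCh38, which held 16553 of the IDs. Strand use in counting is not given, so overlapping, antisense and readthrough genes, and genes with near-identical copies such as the HLA genes, have uncertain counts.

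Total counts were 11282330 to 12299058 in the MCF7 control libraries, 9703240 to 10412558 in the MCF7 knockdown, 15562278 to 16143645 in the SKBR3 control and 14754138 to 15300567 in the SKBR3 knockdown. Counts in protein-coding genes ran from 3585952 to 10404432. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over replicate pairs was 107.5, and all 16 were kept as separate libraries. CPM, counts scaled to 1e6 per library, were computed with effective library sizes, and the mean ± SD over the 4 libraries of a group (n = 4) is given.

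The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter by group, which kept 17225 genes, and a model of the 4 group means over all 16 libraries with 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The adjusted p of a gene is from this test throughout, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. The comparisons were knockdown against control in each line, the difference of these effects (SKBR3 minus MCF7) and the SKBR3 control against the MCF7 control. Genes called in both lines were counted with a one-sided Fisher exact test. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and where they held 1 to 3 counts it is a ratio with an exact 95% interval. Bounds and intervals cover counting error only.

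There were 32 lists of genes written from textbook knowledge. The lists on the HER2 amplicon, luminal identity, EMT and mesenchymal genes and YAP/TEAD targets were primary, since the series title names these themes. Each list was tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 32 lists in each comparison, and again with an estimated correlation. Camera asks whether the genes of a list rank above or below the other genes. Counts of list members that passed are over all genes tested, and, where so stated, adjusted over the list alone. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named 12 tested genes of the study's themes, and VIM and AXL, which were not in the tested set; the 10 largest rises and falls in each knockdown comparison and the 5 largest in the other comparisons, with a mean CPM of at least 5 and, except for the difference, no overlap between groups; up to 4 members per list; and the 5 strongest genes called in both lines in each direction. List members named beside a count without a value of their own lay outside this rule and were named after their values were seen.

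The procedure was tested on simulated counts with the means and library sizes of these libraries and 200 changed genes. For the MCF7 comparison (16516 genes) edgeR recovered 2 of 67 genes changed 2-fold, 32 of 67 changed 4-fold and 39 of 66 changed 8-fold, with 6 false calls. For SKBR3 (16564 genes) these were 1, 22 and 42 with 0 false calls, and for the difference (16493 genes) 0, 3 and 27 with 2 false calls. DESeq2 (version 1.42.0) recovered 7, 45 and 49 for MCF7 with 42 false calls, 6, 31 and 50 for SKBR3 with 32, and 2, 20 and 36 for the difference with 21, all over 17225 genes. A list whose members were all lowered 2-fold was called in each line, and 0 of 31 and 0 of 29 lists without changed genes were.

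Alternatives were DESeq2's size factors, library totals alone, no filter on low counts, a stricter filter, the replicate number as a block, DESeq2's Wald test, robust variance estimates, the 8 libraries of a comparison alone, the estimated correlation, fry in place of camera and each library left out in turn. Counting protein-coding genes alone, and leaving out both knockdown libraries numbered 4, were added after seeing the data. With library totals alone, the median log2 fold change of genes with a CPM of at least 5 moved by -0.107 in MCF7, -0.277 in SKBR3, -0.150 for the difference and -0.486 for the controls, so changes are relative to the TMM scaling. Genes of the sex chromosomes that mark sex were left out of the text. Figures were drawn with matplotlib 3.10.9.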

Results

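Gene expression was measured by RNA sequencing in control and SPDEF knockdown cells of 2 breast cancer lines, MCF7 and SKBR3, with 4 libraries in each of the 4 groups. The series concerns SPDEF, FOXA1, luminal identity, the HER2 pathway and TEAD/YAP-driven epithelial to mesenchymal transition (EMT). On log CPM, the first principal component (48.7% of the variance) separated the lines and the second (17.9%) separated the SKBR3 knockdown from the SKBR3 control. A few libraries stood apart within their group. In SKBR3 knockdown replicate 4, the small nuclear RNA 7SK took 65.2% of the counts and protein-coding genes 23.5%, and the median count per gene was 38. In MCF7 knockdown replicate 4, the readthrough gene RPS10-NUDT3 took 4.57% of the counts, against at most 0.00243% in the other 3. Its median count was 60. The RNA RMRP took 6.15% in SKBR3 control replicate 2 and 10.8% in SKBR3 knockdown replicate 3.

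SPDEF fell in all knockdown libraries of both lines. SPDEF (ENSG00000124664; chromosome 6, 34537802 to 34556333, GRCh38, protein-coding) fell in MCF7 from 25.6 ± 2.16 to 1.88 ± 0.60 CPM (n = 4 each), with counts of 350, 414, 357 and 451 in the control and 35, 18, 30 and 11 in the knockdown. Its log2 fold change was -3.75 (SE 0.45, edgeR adjusted p = 0.000368). In SKBR3, SPDEF fell from 90.8 ± 12.8 to 0.149 ± 0.175 CPM, with counts of 1387, 1198, 1045 and 1724 in the control and 4, 5, 0 and 0 in the knockdown (log2 fold change -8.91, SE 0.59, adjusted p = 7.58e-08). The fall was larger in SKBR3 than in MCF7, with a log2 difference of -5.15 (SE 0.67, adjusted p = 8.01e-05). The SKBR3 control held more SPDEF than the MCF7 control (log2 fold change 1.83, SE 0.41, adjusted p = 0.00215). This call was lost with library totals alone (1.34, adjusted p = 0.0630).

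**Figure D1:**
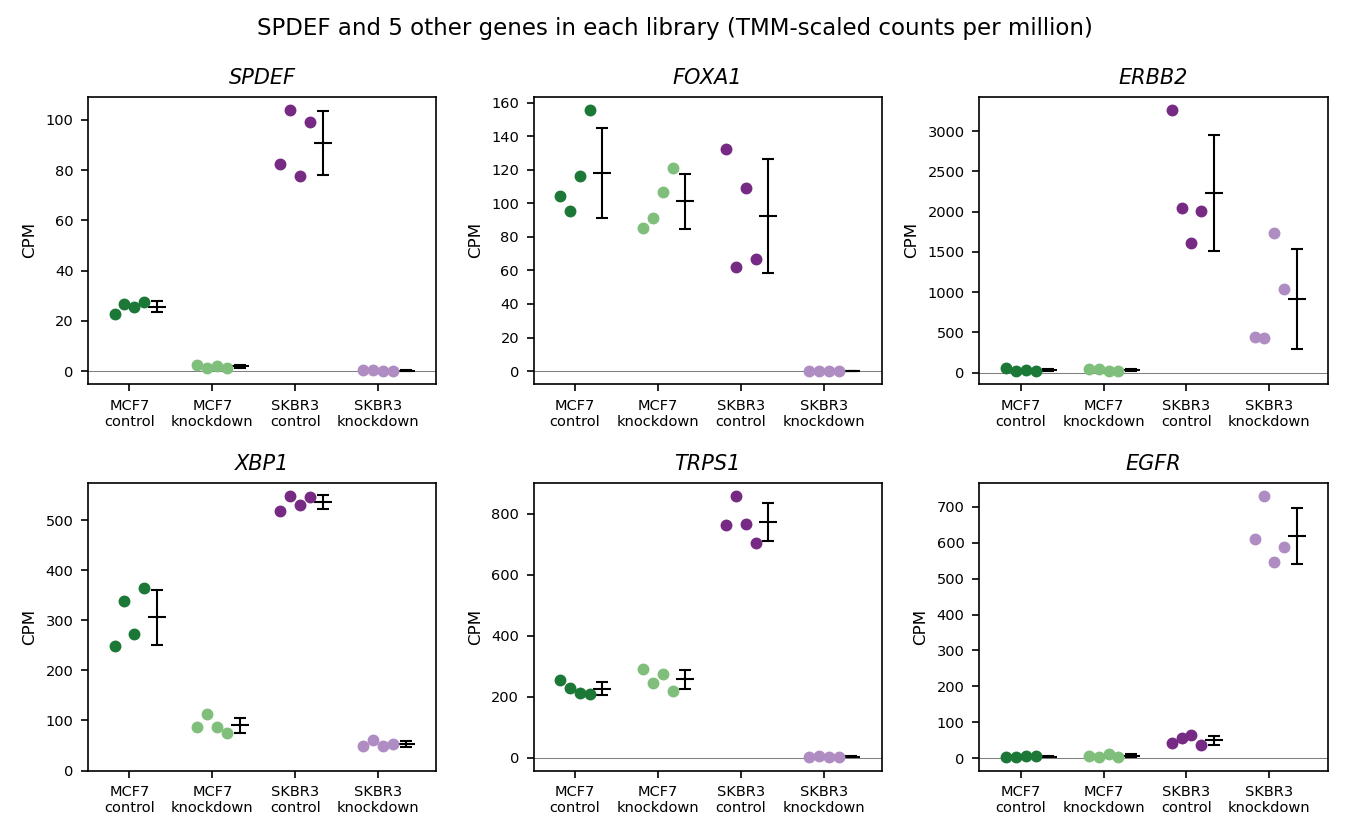
CPM of SPDEF, FOXA1, ERBB2, XBP1, TRPS1 and EGFR in each of the 16 libraries, with points for libraries and bars for the mean ± SD of the 4 libraries of a group. SPDEF fell from 25.6 to 1.88 CPM in MCF7 and from 90.8 to 0.149 in SKBR3, and FOXA1 fell from 92.5 to 0.0994 in SKBR3.

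Genes of the interferon response were lower in the MCF7 knockdown than in its control. Of 24 tested interferon response genes, 21 fell and 0 rose (23 fell when adjusted over the list alone), with a median log2 fold change of -3.14. Neither the unadjusted p nor DESeq2 gave a rise in this list: 0 rose and 23 fell under both. The antiviral protein gene IFIT1 fell from 86.5 ± 19.3 to 2.63 ± 0.555 CPM (log2 fold change -5.03, SE 0.35, edgeR adjusted p = 1.87e-06). MX1 fell from 56.3 ± 13.3 to 0.852 ± 0.323 CPM (-6.00, SE 0.58, adjusted p = 5.69e-05). IFI44 and IFI44L had log2 fold changes of -6.18 and -4.99, and MX2 was 53.9-fold lower (interval 14.6 to 449), with 136 counts in the control and 2 in the knockdown. The list was called by camera (adjusted p = 3.58e-93, and 2.36e-08 with an estimated correlation). Antigen presentation genes fell too: 7 of 17 fell and 0 rose (10 fell adjusted over the list alone; 10 at an unadjusted p under 0.05 and 9 by DESeq2, with 0 rises in each). Among them were the immunoproteasome subunits PSMB8 and PSMB9 (log2 fold changes -4.56 and -3.69), the HLA class II gene HLA-DRB1 (-4.24) and the peptide transporter TAP2 (-2.29). Without MCF7 control replicate 3 the value of PSMB9 was -2.94, and without MCF7 knockdown replicate 3 that of PSMB8 was -6.08. The adjusted p of camera was 1.56e-15, and 0.000729 with an estimated correlation.

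**Figure D2:**
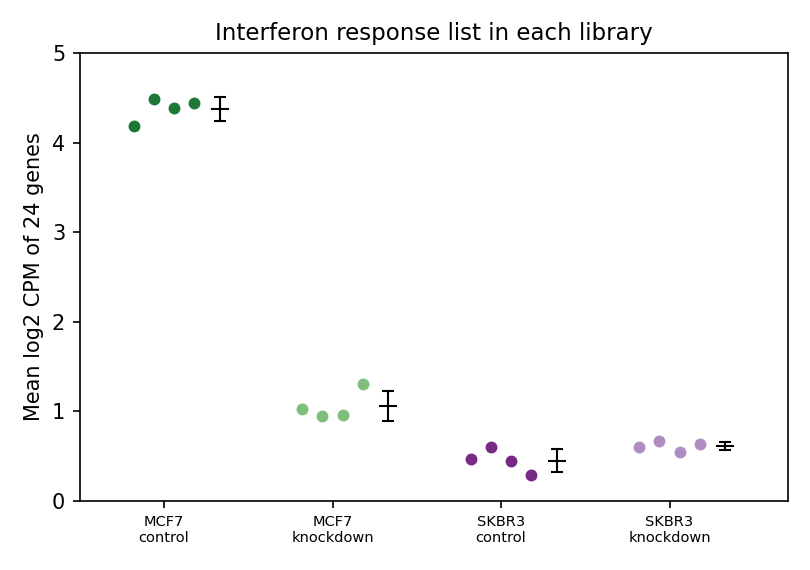
Mean log2 CPM of the 24 interferon response genes in each library, one point per library, by group. The MCF7 control libraries lay at 4.18 to 4.49 and the MCF7 knockdown libraries at 0.949 to 1.30, while the SKBR3 control libraries lay at 0.287 to 0.593.

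Luminal and estrogen response genes were lower in the MCF7 knockdown as groups, with few single genes called. Of 29 luminal identity genes 3 fell and 0 rose (5 fell adjusted over the list alone; 6 at an unadjusted p under 0.05 and 4 by DESeq2, with 0 rises). Among them was XBP1, a transcription factor of the secretory pathway (306 ± 54.9 to 90.1 ± 15.5 CPM; log2 fold change -1.76, SE 0.23, edgeR adjusted p = 0.000595). The others were ELAPOR1 (-2.66) and ZG16B (-1.54). With library totals alone the calls of XBP1 (adjusted p = 0.0566) and ZG16B (adjusted p = 0.0673) were lost. The list had a camera adjusted p of 2.49e-05, and of 0.0017 with an estimated correlation. Of 25 estrogen response genes 2 fell and 0 rose (8 fell adjusted over the list alone; 9 at an unadjusted p under 0.05 and 9 by DESeq2, with 0 rises), XBP1 and PDZK1 (-2.15), with a camera adjusted p of 7.36e-07 (0.00152 with an estimated correlation). The main luminal regulators did not pass. FOXA1 was at 118 ± 26.7 and 101 ± 16.3 CPM (adjusted p = 0.886), GATA3 at 157 ± 13.6 and 281 ± 62.5 (adjusted p = 0.408) and ESR1, the estrogen receptor, at 224 ± 18.8 and 141 ± 48.2 (adjusted p = 0.701).

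Genes of the amino acid response rose in the MCF7 knockdown. Of 19 targets of the stress factor ATF4, 5 rose and 0 fell (6 rose adjusted over the list alone; 7 at an unadjusted p under 0.05 and 6 by DESeq2, with 0 falls), with a camera adjusted p of 1.38e-05 (0.00388 with an estimated correlation). The log2 fold changes were 1.96 for CHAC1, 1.72 for ATF3, 1.52 for the cystine transporter SLC7A11 and 1.10 for asparagine synthetase ASNS, and DDIT4 rose too. The first 4 calls were lost with library totals alone (adjusted p = 0.0861 for CHAC1, 0.114 for ATF3, 0.225 for SLC7A11 and 0.301 for ASNS). In the list of immediate early genes 1 of 16 rose, ATF3, and 0 fell (3 rose adjusted over the list alone; 7 at an unadjusted p under 0.05 and 4 by DESeq2, with 0 falls). That list had a camera adjusted p of 6.71e-05, and its call was lost with an estimated correlation (adjusted p = 0.154).

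The HER2, EMT and YAP/TEAD lists were not called in MCF7. Of 12 genes of the HER2 amplicon, the stretch of chromosome 17 amplified with ERBB2, edgeR called 0 (0 adjusted over the list alone, 1 lower at an unadjusted p under 0.05 and 0 by DESeq2), with a camera adjusted p of 0.944. ERBB2 (ENSG00000141736; chromosome 17, 39687914 to 39730426) was at 32.6 ± 15.3 CPM in the control and 30.7 ± 13.9 in the knockdown (adjusted p = 0.971). Of 24 EMT genes 1 rose, the transcription factor SNAI2 (log2 fold change 3.48), and 0 fell (2 rose and 2 fell adjusted over the list alone; 4 and 4 at an unadjusted p under 0.05, 3 and 2 by DESeq2). The camera adjusted p of this list was 0.939, and its median of -0.17 and the camera direction differed in sign. Of 18 YAP/TEAD targets CCN2 rose (1.87; lost with library totals alone, adjusted p = 0.167) and NT5E fell (-2.37), with 4 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.944). Here too the median of 0.06 and the camera direction differed in sign. YAP1 (log2 fold change -0.38, adjusted p = 0.54), WWTR1 (adjusted p = 1), TEAD1 (0.43, adjusted p = 0.722), TEAD4 (-1.11, adjusted p = 0.0541), CCN1 (0.53, adjusted p = 0.735) and the cadherin gene CDH1 (430 ± 29 to 353 ± 76.0 CPM, adjusted p = 0.881) did not pass. TEAD4 passed by DESeq2 (adjusted p = 0.00753), without replicate 4 of the MCF7 control (adjusted p = 0.0417) or of the MCF7 knockdown (adjusted p = 0.0331) and without both knockdown libraries numbered 4 (adjusted p = 0.0407). TEAD1 and CCN1 were at -0.26 and -0.42 without MCF7 knockdown replicate 2, and ERBB2 at 0.22 without MCF7 control replicate 1, 0.09 without MCF7 knockdown replicate 3 and 0.06 without MCF7 knockdown replicate 4. The other 23 lists were not called either, with camera adjusted p from 0.130 to 0.981. Genes in them that passed included GDF15 (log2 fold change 1.93), the cell cycle inhibitor CDKN2B (1.43), the MAPK target PHLDA1 (-1.95), the chaperone cofactor BAG3 (-1.73) and the lipid enzymes ELOVL5 (-1.17) and ACSL1 (-1.06). These 6 calls were lost with library totals alone (adjusted p = 0.129 for GDF15, 0.146 for CDKN2B, 0.0526 for PHLDA1, 0.0657 for BAG3, 0.278 for ELOVL5 and 0.309 for ACSL1).

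Among the 10 largest rises in MCF7 were CGA, the alpha subunit of glycoprotein hormones (log2 fold change 5.38, SE 0.58, edgeR adjusted p = 0.000181), the prohormone convertase PCSK2 (4.09, SE 0.50, adjusted p = 0.000402) and the protease inhibitor SERPINE2 (0.562 ± 0.298 to 9.50 ± 5.75 CPM; 4.05, adjusted p = 0.00196). The other 7 rested in part on MCF7 knockdown replicate 4, the library rich in RPS10-NUDT3. Without it, log2 fold changes went from 6.23 to 2.78 for ACTG2 (adjusted p = 0.171), from 5.62 to 4.83 for EMP3, from 4.37 to 2.28 for INPP5K, from 3.73 to 1.77 for CLU, from 3.63 to 1.71 for IRF6 (adjusted p = 0.0573), from 3.51 to 2.12 for RFTN1 (adjusted p = 0.0733) and from 3.08 to 1.64 for TFPI. SNAI2 went from 3.48 to 2.64. With the 8 MCF7 libraries alone the calls of ACTG2 (adjusted p = 0.143), INPP5K (0.118), CLU (0.155), IRF6 (0.137), RFTN1 (0.0929) and TFPI (0.129) were lost, and so was ACTG2 without both knockdown libraries numbered 4 (0.188). The largest falls, besides the interferon genes, were those of GBP3, an interferon-induced GTPase (-7.64), SGCE (-7.11), TENM3 (-6.98), TDRD1 (-6.87), the calcitonin receptor CALCR (-6.39) and the phosphodiesterase PDE4B (-5.01). GBP3 was at -6.34 without MCF7 control replicate 1 and -9.17 without MCF7 knockdown replicate 2, and PDE4B at -5.63 without the latter.

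In total edgeR called 341 of 17225 genes in MCF7, 109 higher and 232 lower, of which 107 and 229 changed at least 2-fold. Scaled by library totals alone, 34 were higher and 127 lower, DESeq2 called 1046, and without MCF7 control replicate 4 edgeR called 222. Of the 47 named genes called besides SPDEF, 14 lost their call when some single library was left out, with the highest adjusted p at 0.0904 for CCN2, 0.171 for ACTG2, 0.0760 for INPP5K, 0.0931 for CLU, 0.105 for IRF6, 0.0973 for RFTN1, 0.0972 for TFPI, 0.0694 for TIMP3, 0.0911 for ZG16B, 0.126 for SNAI2, 0.0744 for ATF3, 0.0950 for SLC7A11, 0.119 for GDF15 and 0.0612 for ELOVL5.

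Luminal identity genes were lower in the SKBR3 knockdown than in its control. Of 29, 18 fell and 2 rose (18 and 2 adjusted over the list alone), with a median log2 fold change of -2.61 and a camera adjusted p of 1.92e-10 (0.000158 with an estimated correlation). FOXA1 (ENSG00000129514; chromosome 14, 37589984 to 37596059), a pioneer factor of luminal cells, fell from 92.5 ± 33.8 to 0.0994 ± 0.158 CPM. Its counts were 2221, 717, 1466 and 1159 in the control and 5, 1, 0 and 0 in the knockdown (log2 fold change -9.48, SE 0.69, edgeR adjusted p = 1.75e-07; -11.18 without SKBR3 knockdown replicate 1). The transcription factor TRPS1 fell from 773 ± 63.8 to 3.46 ± 2.38 CPM (-7.78, SE 0.52, adjusted p = 8.11e-08). So did the carbonic anhydrase CA12 from 237 ± 25.4 to 1.46 ± 1.39 CPM (-7.28, SE 0.58, adjusted p = 3.96e-07; -8.13 without SKBR3 knockdown replicate 1) and XBP1 from 536 ± 13.7 to 53.3 ± 5.73 CPM (-3.33, SE 0.24, adjusted p = 1.57e-07). ELAPOR1 fell (-4.97), and ZG16B was 327-fold lower (interval 90.1 to 2701.5). The genes that rose were TBX3 and GATA3, a luminal transcription factor (1.41 ± 1.51 to 6.45 ± 0.498 CPM; 2.21, adjusted p = 0.00427; 3.27 without SKBR3 control replicate 2). ESR1 was low in both arms (1.82 ± 2.70 to 0.275 ± 0.133 CPM). Its fall (-2.62, adjusted p = 0.0257) rested on SKBR3 control replicate 3, without which it was -0.71 (adjusted p = 0.317), and was lost without both knockdown libraries numbered 4 (adjusted p = 0.0572).

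MAPK output genes were lower in SKBR3 as a group, and so were androgen response genes, but the androgen call (camera adjusted p = 0.01) was lost with an estimated correlation (adjusted p = 0.0916). Of 17 androgen response genes 9 fell and 4 rose, NKX3-1, ABCC4, ZBTB10 and HERC3 (9 and 4 adjusted over the list alone). Those that fell included TARP (log2 fold change -8.57, within the T cell receptor gamma locus and so of uncertain count), the aldehyde dehydrogenase ALDH1A3 (-6.14) and PMEPA1 (-5.31). The androgen call was also lost with protein-coding genes alone (adjusted p = 0.115), without both knockdown libraries numbered 4 (adjusted p = 0.0686) and with the 8 SKBR3 libraries alone (adjusted p = 0.0571). Of 16 MAPK output genes 9 fell and 1 rose, ETV5 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000149, and 0.0382 with an estimated correlation). The phosphatases of this pathway DUSP4 and DUSP6 fell (-4.23 and -3.92), as did the ETS factor ETV4 (-3.83; -3.15 without SKBR3 control replicate 3). In the estrogen response list 4 rose and 7 fell of 25 (4 and 8 adjusted over the list alone; camera adjusted p = 0.122), with STC2 at 6.55 (9.81 without SKBR3 control replicate 4).

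The HER2 amplicon list was not called in SKBR3. Of its 12 genes 3 fell, PPP1R1B (log2 fold change -2.09), the adaptor GRB7 (-1.24) and TCAP, and the transcription factor IKZF3 rose (2.42), with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.423). ERBB2 was at 2232 ± 717 CPM in the control and 910 ± 621 in the knockdown, a log2 fold change of -1.29 (SE 0.51) that did not pass (edgeR adjusted p = 0.0777). The 4 knockdown libraries were at 439, 427, 1738 and 1037 CPM. ERBB2 passed without SKBR3 knockdown replicate 3 (-1.81, adjusted p = 0.0225), with library totals alone (adjusted p = 0.0418) and by DESeq2 (adjusted p = 0.0361). The call of GRB7 was lost without any of 12 of the libraries (highest adjusted p = 0.123), with the size factors of DESeq2 (0.0652), with the stricter filter (0.0569) and with protein-coding genes alone (0.0586). Among 13 ERBB ligands and receptors, 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.324). The epidermal growth factor receptor EGFR rose from 49 ± 12.4 to 619 ± 78.9 CPM (3.66, SE 0.48, adjusted p = 4.83e-05). The ligand EGF fell (-5.35), and so did the receptor inhibitor LRIG1 (-4.87; -5.61 without SKBR3 knockdown replicate 2) and the ligand BTC (-4.75). Without SKBR3 control replicate 3 BTC was at -2.63 (adjusted p = 0.0517), and without SKBR3 knockdown replicate 3 at -6.95.

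The EMT list was called higher in the SKBR3 knockdown by camera (adjusted p = 0.01), but not with an estimated correlation (adjusted p = 0.0767). Splits of the libraries did not decide on chance. In all, 2 of 35 were as small, the real one included, but the other kept most libraries of each arm together. Of 24 genes, 7 rose and 2 fell, TGFBI and PLAUR (7 and 2 adjusted over the list alone). The median log2 fold change was 0.94, or 1.19 with genes of 0 to 3 counts in a group set at their bound or ratio. SPARC, a matrix protein, rose from 0.0186 ± 0.0371 to 726 ± 228 CPM, a ratio of 39051 (interval 7008 to 1542460; 1 count in the control). The collagen chain COL6A1 was 450-fold higher (interval 124 to 3724) and the integrin subunit ITGA5 rose (4.19, edgeR adjusted p = 0.00102). TGFBI fell (-4.81; -8.85 without SKBR3 knockdown replicate 4, which held all of its knockdown counts). VIM, CDH2, ZEB1, ZEB2 and TWIST1 were not in the tested set. CDH1 was near 0 in both arms (0.0888 ± 0.142 and 0.131 ± 0.120 CPM, adjusted p = 0.804), and its direction turned without SKBR3 knockdown replicate 2 (-0.49). Among 27 genes of epithelial junctions and splicing 3 rose, CLDN4, MARVELD3 and ESRP1, and 7 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.547). RAB25 fell (-6.98; -6.13 without SKBR3 control replicate 3), as did MAL2 (-3.17; -2.15 without SKBR3 control replicate 2) and TJP3 (-2.65; -1.46 without SKBR3 control replicate 4), while ESRP1 was at 3.15 (2.27, adjusted p = 0.0537, without SKBR3 knockdown replicate 2).

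YAP/TEAD targets were not called in SKBR3, whereas some TEAD cofactors and regulators rose. Of 18 targets 4 rose, NUAK2 (log2 fold change 2.40), NT5E (2.23), LATS2 and IGFBP3, and 2 fell, CCN2 (-1.64, edgeR adjusted p = 0.0014) and TGFB2 (-4.20), with 4 and 3 adjusted over the list alone (camera adjusted p = 0.349). The call of TGFB2 was lost without any of 12 of the libraries, with -3.54 (adjusted p = 0.112) without SKBR3 control replicate 3, and without both knockdown libraries numbered 4 (adjusted p = 0.0565). It was at -5.86 without SKBR3 knockdown replicate 1. Of 20 Hippo and TEAD factors 7 rose and NF2 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0885, which passed with library totals alone, at 0.0270, and with the 8 SKBR3 libraries alone, at 0.0357). The angiomotin gene AMOT rose from 0.0876 ± 0.0753 to 112 ± 44.8 CPM (10.22, SE 0.96, adjusted p = 1.9e-06). The TEAD cofactor VGLL3 had a log2 fold change of 7.98, and the kinase activator MOB1B of 2.12. TEAD1 rose from 66.8 ± 19.5 to 235 ± 83.9 CPM (1.82, adjusted p = 0.00859; lost with library totals alone, adjusted p = 0.0746). YAP1 rose from 54.4 ± 15.8 to 91.1 ± 20.7 CPM (0.74, adjusted p = 0.0485), and this call was lost without any of 7 of the libraries (adjusted p = 0.122 without SKBR3 control replicate 3), with library totals alone (0.457), with the 8 SKBR3 libraries alone (0.0919) and without both knockdown libraries numbered 4 (0.0644). WWTR1 (0.28, adjusted p = 0.697), TEAD4 (-0.09, adjusted p = 0.843; 0.02 without SKBR3 control replicate 4) and CCN1 (-0.82, adjusted p = 0.293) did not pass.

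Basal, inflammatory and antigen presentation genes were higher in the SKBR3 knockdown with the preset correlation, and these calls were lost with an estimated one. Of 18 basal epithelium genes 10 rose and 2 fell, KRT15 and SFN (12 and 3 adjusted over the list alone; camera adjusted p = 0.00502, and adjusted p = 0.0949 with an estimated correlation). The integrin subunit ITGA6 rose (log2 fold change 7.57; 9.12 without SKBR3 control replicate 4), as did TP63, a basal transcription factor (5.22; 5.88 without that library), and FOXC1 was 226-fold higher (interval 40.1 to 8989). KRT15 was at -4.35 (-3.38 without SKBR3 control replicate 2). The basal genes KRT5, KRT14, KRT6A, KRT6B, S100A2 and MIA were not in the tested set. Of 16 NF-kB and inflammatory genes 7 rose and 0 fell (8 rose and 1 fell adjusted over the list alone; 8 and 1 at an unadjusted p under 0.05, 7 and 1 by DESeq2), with a camera adjusted p of 0.00441 and an adjusted p of 0.0687 with an estimated correlation. Examples were CCL2 (3.68), TNF (3.30) and TNFAIP3 (2.89, and 2.07 without SKBR3 knockdown replicate 4). CXCL1, CXCL2, CXCL3, CXCL8, IL1A, IL1B, PTGS2 and TRAF1 of this list were not in the tested set. Of 17 antigen presentation genes 6 rose and 0 fell (8 and 0 adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2), with PSMB9 at 4.63, TAP1 at 2.71 and HLA-C at 1.92 (camera adjusted p = 0.0124, and adjusted p = 0.174 with an estimated correlation). The interferon response list went both ways, with 6 of 24 higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.654). In it IFIT3 rose (4.28), HERC5 was 195-fold higher (interval 66.4 to 950) and BST2 was 82.2-fold lower (interval 22.5 to 684).

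Of the markers of other cell types, 3 of 4 tested fibroblast genes rose in the SKBR3 knockdown (3 adjusted over the list alone), COL3A1, the microfibril gene MFAP5 (log2 fold change 7.43) and FBLN1, which was already at 121 CPM in the control (1.71; lost with library totals alone, adjusted p = 0.0577). The camera adjusted p was 0.0259. The call was lost with an estimated correlation (adjusted p = 0.0916), with the 8 SKBR3 libraries alone (adjusted p = 0.0941) and without both knockdown libraries numbered 4 (adjusted p = 0.0686). The fibroblast genes COL1A2, DCN and LUM were not in the tested set. Of 6 endothelial genes KDR, FLT1 and CDH5 rose and ESAM fell (the same numbers adjusted over the list alone; camera adjusted p = 0.362), with CDH5 at 2.53 (1.91, adjusted p = 0.0723, without SKBR3 knockdown replicate 3). None of 3 leukocyte genes was called by edgeR in SKBR3 (0 adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2). The remaining lists of SKBR3 were not called, with camera adjusted p from 0.0679 for TGF-beta response (4 higher and 9 lower of 20; 4 and 10 adjusted over the list alone) to 0.981 for p53 targets. TGF-beta response passed with library totals alone (adjusted p = 0.0321), with the stricter filter (adjusted p = 0.0306), with the 8 SKBR3 libraries alone (adjusted p = 0.0116) and without MCF7 control replicate 1 (adjusted p = 0.0405), SKBR3 control replicate 1 (0.0387) or 4 (0.0222), or SKBR3 knockdown replicate 2 (0.0456). Members that passed included DDIT4 (-3.81) and MTHFD2 (-2.49; -1.20 without SKBR3 control replicate 2) of the ATF4 list, the fatty acid desaturases FADS2 (8.95) and FADS1 (8.64; 7.71 without SKBR3 knockdown replicate 2), HMGCS1 of cholesterol synthesis (2.10). Cell cycle members were TK1 (-2.69; -1.64 without SKBR3 control replicate 3) and AURKB (2.69; 1.72 without SKBR3 knockdown replicate 4).

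The 10 largest rises in SKBR3, besides that of SPARC, included genes without a count in the 4 control libraries. The protease HTRA1 was at least 921-fold higher, the channel HCN1 at least 782-fold, SIGLEC5 at least 576-fold (2 gene IDs share this symbol), MGARP at least 381-fold, CARD11, an NF-kB scaffold, at least 368-fold and SEMA6D at least 288-fold higher. The amino acid transporter SLC7A2 was 4739-fold higher (interval 1311.5 to 39140.5), and the RNA-binding protein IGF2BP2 (log2 fold change 11.14; 10.52 without SKBR3 knockdown replicate 3) and the metalloproteinase ADAMTS1 (11.02; 12.33 without SKBR3 control replicate 1) rose. The largest falls besides FOXA1 and SPDEF included genes without a count in the knockdown. The mucin MUC19 was at least 473-fold lower, SRARP at least 235-fold, the hedgehog receptor PTCH1 at least 218-fold, the ephrin EFNA5 at least 200-fold, NCKAP5 at least 168-fold and FOLH1 at least 159-fold lower. The transcription factors MECOM and IRX3 were 2062-fold lower (interval 370 to 81465) and 1726-fold lower (interval 309 to 68189), and SQOR was 1220-fold lower (interval 219 to 48229).

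In total edgeR called 4458 genes in SKBR3, 2062 higher and 2396 lower, and 1837 and 2070 of these changed at least 2-fold. Scaled by library totals alone, 1200 were higher and 2298 lower. Without both knockdown libraries numbered 4, edgeR called 303 genes in MCF7 and 4871 in SKBR3, and with protein-coding genes alone 318 and 3858.

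**Figure D3:**
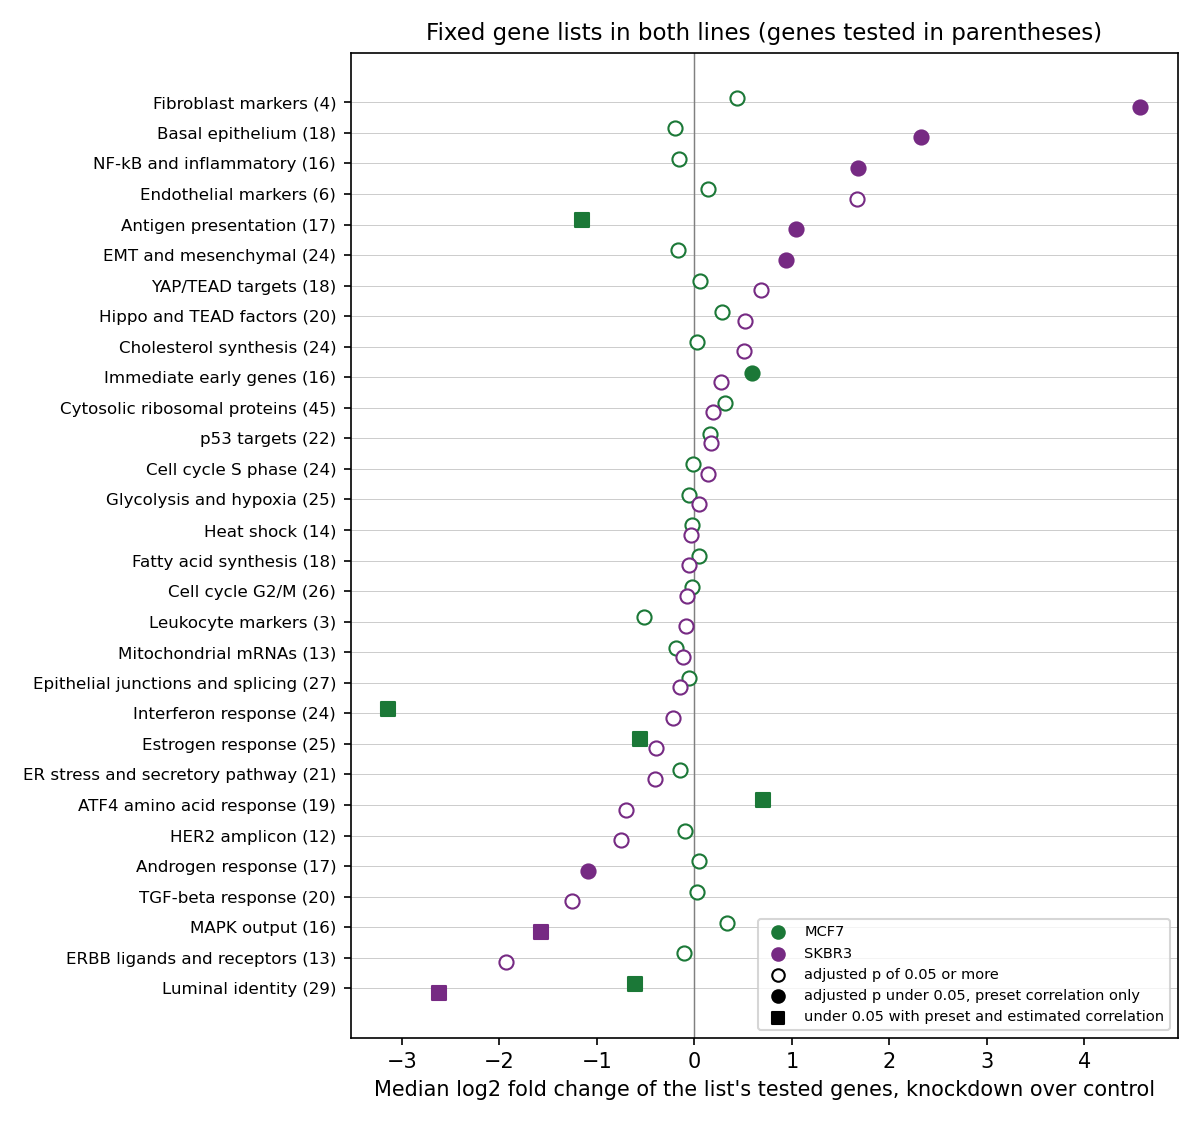
Median log2 fold change, knockdown against control, of the tested genes of 30 lists in MCF7 and SKBR3. Open circles are lists with a camera adjusted p of 0.05 or more, filled circles lists called with the preset correlation alone, and squares lists called with the preset and the estimated correlation, such as the interferon response in MCF7 (median -3.14) and luminal identity in SKBR3 (median -2.61).

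Both lines changed some of the same genes, in the same and in opposite directions. The overlap thus does not show a shared direction of response. Of the 17225 genes, 28 were higher in both lines, against 13.0 for independent lists (one-sided Fisher exact p = 6.15e-05), and 61 were lower in both, against 32.3 (p = 4.00e-07). Opposite calls were also more common than for independent lists: 64 genes were lower in MCF7 and higher in SKBR3, against 27.8 (Fisher's exact test, p = 6.88e-11), and 24 were higher in MCF7 and lower in SKBR3, against 15.2 (p = 0.0138). Across all genes, which are not independent replicates, Spearman's rho of the log2 fold changes was -0.048. The strongest shared rises were those of SERPINE2 (log2 fold changes 4.05 in MCF7 and 8.83 in SKBR3; 9.74 without SKBR3 control replicate 2), TFPI (3.08 and 3.81), the integrin subunit ITGB6 (2.43 and 1.36), the cholesterol transporter ABCA1 (1.9 and 4.51) and the metalloproteinase inhibitor TIMP3 (1.38 and 3.35). With library totals alone the MCF7 calls of TFPI (adjusted p = 0.0673), ABCA1 (0.0548), TIMP3 (0.279) and XBP1 (0.0566) were lost, as was the SKBR3 call of ITGB6 (0.109). The strongest shared falls were those of ELAPOR1 (-2.66 and -4.97), TDRD1 (-6.87 and -2.49), the interferon-induced protease USP18 (-2.35 and -2.25), XBP1 (-1.76 and -3.33) and CLEC3A (-2.29 in MCF7, and 505-fold lower in SKBR3 with an interval of 90.4 to 19991). The count of shared rises was 17, 16 and 16 without MCF7 control replicates 1, 2 and 4.

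The effect of knockdown differed between the lines for 2954 genes, 1443 with a higher and 1511 with a lower value in SKBR3. FOXA1 differed (log2 difference -9.25, SE 0.80, edgeR adjusted p = 1.77e-06; -10.96 without SKBR3 knockdown replicate 1), as did CCN2 (-3.51, SE 0.49, adjusted p = 0.000158). ERBB2 did not pass (-1.20, SE 0.72, adjusted p = 0.26), nor did GATA3 (1.37, adjusted p = 0.171), ESR1 (-1.95, adjusted p = 0.199), CDH1 (0.65, adjusted p = 0.713), WWTR1 (0.28, adjusted p = 0.807), TEAD1 (1.39, adjusted p = 0.142), TEAD4 (1.02, adjusted p = 0.0782) and CCN1 (-1.35, adjusted p = 0.255). Of these, all but ERBB2 depended on single libraries. GATA3 passed without SKBR3 control replicate 2 (2.43, adjusted p = 0.000375) and TEAD1 without MCF7 knockdown replicate 2 (2.13, adjusted p = 0.00954). TEAD4 passed without replicate 4 of the MCF7 control (1.22, adjusted p = 0.0444) or of the MCF7 knockdown (1.21, adjusted p = 0.0406), without both knockdown libraries numbered 4 (adjusted p = 0.0445) and by DESeq2 (adjusted p = 0.0431). ESR1 was at -0.05 without SKBR3 control replicate 3, and CCN1 was at -0.36 and WWTR1 at -0.01 without MCF7 knockdown replicate 2. CDH1 was at 2.37 without SKBR3 control replicate 1 and at -0.20 without SKBR3 knockdown replicate 2. YAP1 passed narrowly (1.12, adjusted p = 0.0499) and was lost without any of 11 of the libraries (highest adjusted p = 0.0886), with library totals alone (0.347), without a filter on low counts (0.0504) and without both knockdown libraries numbered 4 (0.103). Of the lists, interferon response (14 of 24 higher, also 14 adjusted over the list alone, camera adjusted p = 1.81e-15), antigen presentation (9 of 17 higher, 11 adjusted over the list alone, adjusted p = 5.60e-08), basal epithelium (7 of 18 higher, 8 adjusted over the list alone, adjusted p = 0.000286), NF-kB (4 higher and 1 lower of 16, the same adjusted over the list alone, adjusted p = 0.00454) and EMT (8 higher and 2 lower of 24, 8 and 3 adjusted over the list alone, adjusted p = 0.00818) had higher values in SKBR3. Luminal identity (1 higher and 10 lower of 29, the same adjusted over the list alone, adjusted p = 4.28e-06), MAPK output (7 of 16 lower, 8 lower and 1 higher adjusted over the list alone, adjusted p = 0.000152), ATF4 targets (7 of 19 lower, 8 adjusted over the list alone, adjusted p = 0.000974), androgen response (2 higher and 7 lower of 17, 3 and 9 adjusted over the list alone, adjusted p = 0.00359) and TGF-beta response (3 higher and 9 lower of 20, 4 and 12 adjusted over the list alone, adjusted p = 0.01) had lower values there. The call of TGF-beta response alone among these was lost with an estimated correlation (adjusted p = 0.0589), and that of androgen response with protein-coding genes alone (adjusted p = 0.0801). The HER2 amplicon (adjusted p = 0.845) and YAP/TEAD targets (adjusted p = 0.391) did not differ past the threshold.

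The largest single differences included EDIL3 (log2 difference 15.28; 13.10 without MCF7 control replicate 1), TENM3 (14.59; 21.41 without SKBR3 control replicate 1), HMCN1 (13.09; 9.36 without SKBR3 knockdown replicate 1), PDZRN3 (-12.10; -10.45 without MCF7 knockdown replicate 3), CAPN13 (-11.07; -12.76 without SKBR3 knockdown replicate 2) and the ephrin receptor EPHB6 (-10.87; -13.11 without SKBR3 knockdown replicate 1). The antisense gene DNAJC9-AS1, of uncertain count without strand and with 2 gene IDs, had 15.13, and 9.21 without MCF7 control replicate 1. Where a group of such a gene held 0 to 3 counts, these fitted values depend on the prior count and are no bounds.

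The controls of the lines differed in the ways their labels imply. All 5 genes checked for SKBR3 (ERBB2, GRB7, STARD3, MIEN1 and PGAP3) were higher in the SKBR3 control and all 5 checked for MCF7 (ESR1, GREB1, TFF1, PGR and CDH1) were higher in the MCF7 control (5 and 5 adjusted over the list alone; camera adjusted p = 1.69e-07 for each list). The log2 fold change, SKBR3 against MCF7, was 6.10 for ERBB2 (SE 0.63, edgeR adjusted p = 2.57e-06), 5.30 for GRB7, 5.09 for PGAP3, 4.32 for MIEN1, -6.94 for ESR1, -8.89 for TFF1 and -11.98 for CDH1 (-13.72 without SKBR3 control replicate 1). ESR1 was at -8.84 without SKBR3 control replicate 3. The progesterone receptor PGR was at least 1098-fold lower in SKBR3, and GATA3 was lower there too (-6.82; -7.87 without SKBR3 control replicate 2). FOXA1 did not differ past the threshold (-0.35, adjusted p = 0.559), nor did TEAD1 (0.30, adjusted p = 0.608), while YAP1 (1.46), TEAD4 (2.25), CCN1 (3.07), CCN2 (3.57) and WWTR1 (1.39, adjusted p = 0.0241) were higher in SKBR3. The call of WWTR1 was lost without any of 4 of the libraries (highest adjusted p = 0.0685) and with library totals alone (0.224), as was that of YAP1 (0.0805). Of 12 HER2 amplicon genes 11 were higher (12 adjusted over the list alone, camera adjusted p = 9.34e-13), and of 24 interferon response genes 22 were lower (22 adjusted over the list alone, adjusted p = 6.27e-17). Estrogen response (3 higher and 16 lower of 25, adjusted p = 3.15e-06), basal epithelium (2 and 10 of 18, or 2 and 11 adjusted over the list alone, adjusted p = 0.000509), p53 targets (10 of 22 lower, adjusted p = 0.00402), androgen response (9 and 2 of 17, adjusted p = 7.36e-05) and ATF4 targets (11 and 2 of 19, adjusted p = 0.00415) differed too, and the basal call was lost with an estimated correlation (adjusted p = 0.0502). Luminal identity (10 and 9 of 29, adjusted p = 0.682), EMT (5 and 8 of 24, adjusted p = 0.985) and YAP/TEAD targets (5 of 18 higher, adjusted p = 0.436) were not called, and except for the basal list these counts were the same adjusted over the list alone.

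In all, 7639 genes differed between the controls, 3999 higher and 3640 lower in SKBR3, against 1968 and 4031 scaled by library totals alone. The largest included ZFHX4, TRPM2, CSAG1 and PDGFD, at least 1157-fold, 908-fold, 765-fold and 543-fold higher in SKBR3, and HMCN1, NPY1R, MMP16 and PCDH10, at least 7264-fold, 2809-fold, 2382-fold and 1807-fold lower. The gap junction gene GJA5 was at 11.62 (9.87 without SKBR3 control replicate 2), the keratin KRT7 at 7.64, and SLC7A2 was 17330.5-fold lower (interval 4797 to 143109) and IFI44L 1310-fold lower (interval 235 to 51739).

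**Figure D4:**
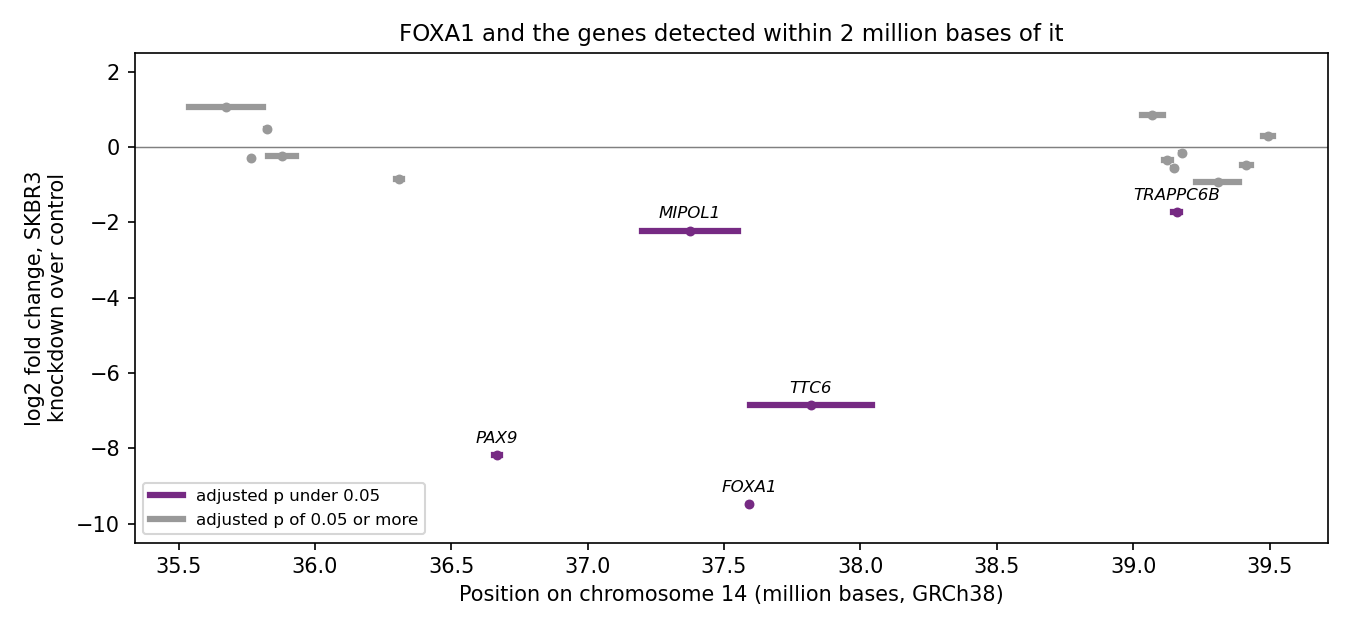
Log2 fold change in SKBR3 of FOXA1 and of the genes with at least 1 CPM in the SKBR3 control within 2 Mb on chromosome 14, by position in GRCh38, with purple for an adjusted p under 0.05. The 16 neighbours had a median of -0.41, against -9.48 for FOXA1. The nearest of them, TTC6, MIPOL1 and PAX9, had -6.86, -2.22 and -8.17.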

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

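The tests of depth, spread, a single library, an effect in both lines, a short deletion and an shRNA that also targets FOXA1, the counts of splits for single lists, and those of splits that kept the SKBR3 arms, were chosen only after the result was seen.

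Many more genes changed in SKBR3 (4458) than in MCF7 (341). Another cell line in the SKBR3 knockdown arm would bring stretches of neighbouring genes with shifted copy number. The variance of medians over 204 windows of 50 neighbouring genes, beyond that of shuffled genes, was 0.138 of that between the controls of the lines (0.128 to 0.154 with 1 library left out). CDH1 stayed near 0 in both SKBR3 arms. Both values argue against another line. The same ratio was 0.0376 for the MCF7 knockdown, so SKBR3 held more regional excess than MCF7, and its cause was not tested. Deeper or more uniform SKBR3 libraries are argued against by mean effective library sizes of 0.964 and a coefficient of variation of 0.997 relative to MCF7. A larger dependence of SKBR3 on SPDEF, or its deeper knockdown there, may explain the pattern and was not tested. Nor can a difference between the cultures or stable lines of the SKBR3 arms, apart from SPDEF, be told apart from the knockdown.

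Interferon genes fell in the MCF7 knockdown. No single library decides this, since the highest adjusted p of the list with 1 library left out was 2.68e-74. An effect of SPDEF loss in both lines stays open only in part. The lines differed (camera adjusted p = 1.81e-15). In the SKBR3 knockdown 6 of 24 genes rose and 5 fell, and a lack of room to fall cannot account for the rises. For the genes not called there the question stays open. The SKBR3 control libraries already lay at a mean log2 CPM of 0.287 to 0.593 over the list. This was below the MCF7 knockdown at 0.949 to 1.30, with little room to fall. A difference in interferon state between the cultures of the arms, apart from SPDEF, may also explain the fall in MCF7. The MCF7 control libraries spanned 0.308 against a difference of means of 3.32. But the labels do not say whether the libraries of an arm came from separate lines or cultures. This explanation thus cannot be told apart from the knockdown. SPDEF loss itself remains the biological candidate, as a hypothesis.

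FOXA1 was almost undetected in the SKBR3 knockdown. Loss of the whole stretch within 2 Mb on either side is argued against by its 16 expressed genes, whose median log2 fold change was -0.41 (-0.41 to -0.05 with 1 library left out). That median does not bear on a shorter stretch, since the detected genes nearest to FOXA1, namely TTC6, MIPOL1 and PAX9, all fell. A short deletion stays open: TTC6 (37595847 to 38041442), which overlaps FOXA1 at its end, had -6.86, PAX9 (36657568 to 36679715) -8.17, while MIPOL1 between them (37197913 to 37552361) had -2.22 and still held 101, 99, 101 and 22 counts. Loss of transcription of these genes, without loss of DNA, would give the same values, and DNA was not analysed here. An shRNA that also targets FOXA1 might lower it, and the value in MCF7 (-0.22) does not exclude this, since the libraries are not labelled by hairpin; FOXA1 loss following SPDEF loss in SKBR3 is the biological candidate and was not tested apart from these.

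Other splits of the 8 libraries of a comparison into 4 and 4 bear on chance. In 35 splits each, the real split called 341 genes in MCF7 against at most 1 in the others. It called 4458 against 2 in SKBR3 and 7639 against 1 between the controls (1 of 35 each, the smallest share possible). These counts thus follow the labels of the libraries, but the other splits mix the groups, which widens the spread within them. Splits of libraries cannot exclude a chance difference between the cultures or lines of the groups. For the difference, 1 of 100 drawn splits reached 2954 genes. The highest other count was 2615. The 5 other splits that kept the real SKBR3 arms called 2210 to 2615 genes, and the 94 remaining splits called 0 to 9, so these high counts follow the SKBR3 arms. The 6 splits that kept these arms are too few for a share under 0.05.

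Splits cannot decide on chance for most numbers of lists that camera called. In MCF7, 7 of 35 splits called at least the real 6 (highest other 7). In SKBR3, 2 of 35 called 8 or more (highest other 8), and for the controls 9 of 35 called 9 or more (highest other 12). The other splits that reached these counts kept most libraries of each group together, so they still held part of the real difference. Splits that divided each group evenly called at most 1 list, though the real difference then widens the spread within them. For the difference 3 of 100 splits reached 10 or more (highest other 11), but the 2 others kept the real SKBR3 arms. Of the 6 splits that kept these arms, the real one included, 3 reached 10, so the number follows the SKBR3 arms. For single lists, counted after the result was seen, only the real split (1 of 35) was as small for the interferon response in MCF7 (lowest other camera adjusted p = 5.15e-17). The same held for luminal identity in MCF7 (0.000178) and in SKBR3 (0.00098). These shares were not adjusted for the number of lists counted. EMT in the difference was as small in 2 of 100 splits (lowest other 0.00659). The other again kept the SKBR3 arms (2 of 6), so here too the share says little on the grouping of MCF7. EMT in SKBR3 was as small in 2 of 35 splits (lowest other 0.00393). The other split kept most libraries of each arm together and so does not decide on chance. In splits that divided each arm evenly the lowest camera adjusted p was 0.168. Chance cannot be excluded for luminal identity in the difference (6 of 100, lowest other 2.69e-10). All 6, the real one included, kept the SKBR3 arms, and 0 of the 94 remaining splits were as small (lowest 0.000817). This share thus follows the SKBR3 arms too.

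Single libraries lay far from the other 3 of their group (Dixon's test at the 95% level) in 14 of 96 groups tested. Chance gives about 4.8 for measures fixed beforehand. Here the measures included the 7SK, RMRP and RPS10-NUDT3 shares, on which these libraries stood apart, so 4.8 is no firm yardstick. Of the library measures these were the total count of SKBR3 knockdown 2 (14754100) and the protein-coding share (23.5%) and the 7SK share (65.2%) of SKBR3 knockdown 4. The RMRP share did so in MCF7 control 1 (0.0621%), SKBR3 control 2 (6.15%) and SKBR3 knockdown 3 (10.8%). So did the RPS10-NUDT3 share (4.57%) and principal component 3 (-145.3) of MCF7 knockdown 4. Of the genes they were ESR1 at 213 CPM, AMOT at 4.15 and CA12 at 115 in MCF7 knockdown 4. The others were ESR1 at 5.86 in SKBR3 control 3 and GATA3 at 3.65 in SKBR3 control 2. SPARC at 0.0742 in SKBR3 control 3 is counted among the 14 but says nothing, since it is a single count beside 3 libraries without any.

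The effect of knockdown differed between the lines, by the test of the difference, for 99 of the 134 genes named for the knockdown comparisons or for the difference. Many of these genes were named for a large change or a large difference, so this share follows from their choice. Of all 17225 genes tested, 2954 differed. Log2 differences, SKBR3 minus MCF7, were higher in SKBR3 for PDZK1 (3.10), STC2 (7.52), ABCA1 (2.61), CALCR (7.83), TDRD1 (4.38), PDE4B (6.06), SGCE (8.57). So were TENM3 (14.59), HMCN1 (13.09), EDIL3 (15.28), DNAJC9-AS1 (15.13), SIGLEC5 (12.99), SLC7A2 (11.96), MGARP (10.80), IGF2BP2 (9.83), IKZF3 (2.99) and AURKB (3.09). Also higher there were SPARC (18.17), HTRA1 (12.33), ADAMTS1 (11.02), COL6A1 (8.79), MFAP5 (7.90), ITGA6 (7.55), ITGA5 (5.25), SERPINE2 (4.78), NT5E (4.60), FBLN1 (2.03) and TIMP3 (1.97). The same held for FOXC1 (7.80), TP63 (5.47), EGFR (3.15), AMOT (12.31), VGLL3 (6.83), NUAK2 (3.36), MOB1B (1.79) and YAP1 (1.12). Values were 9.20 for HERC5, 9.04 for GBP3, 8.83 for IFI44L, 8.10 for IFIT3, 7.49 for IFI6, 6.64 for MX1, 6.28 for IFIT1, 8.31 for PSMB9, 5.50 for PSMB8, 7.64 for HLA-DRB1, 4.40 for TAP1, 3.93 for TAP2, 3.41 for HLA-C, 6.62 for CCL2, 3.90 for TNF and 3.79 for TNFAIP3. They were 8.35 for FADS2, 7.09 for FADS1, 1.99 for HMGCS1 and 1.22 for ELOVL5. Of these 56 genes 12 were run with each library left out, and 9 moved by over 0.585 on the log2 scale. SPARC was at 17.35 without MCF7 control 1, 19.11 without MCF7 knockdown 2 and 19.68 without SKBR3 control 3. EDIL3 was at 13.10 without MCF7 control 1, 16.98 without MCF7 knockdown 3 and 16.74 without SKBR3 control 1. DNAJC9-AS1 was at 9.21 without MCF7 control 1, 16.48 without SKBR3 control 4 and 9.81 without SKBR3 knockdown 3. HMCN1 was at 13.77 without MCF7 knockdown 4 and 9.36 without SKBR3 knockdown 1, and TENM3 at 21.41 without SKBR3 control 1. Others were HERC5 (10.05 without SKBR3 control 1), IFI6 (8.85 without SKBR3 control 2), PSMB9 (7.60 without MCF7 control 3) and EGFR (3.78 without MCF7 knockdown 3).

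Values were lower in SKBR3 for SPDEF (-5.15), FOXA1 (-9.25), TRPS1 (-7.97), CA12 (-6.99), ZG16B (-6.56), ELAPOR1 (-2.31), XBP1 (-1.57), TARP (-8.98), ALDH1A3 (-5.86) and PMEPA1 (-6.47). They were lower for DUSP6 (-4.73), DUSP4 (-4.46), ETV4 (-4.38), LRIG1 (-7.07), GRB7 (-1.98), TGFB2 (-9.64), TGFBI (-4.64), CCN2 (-3.51), CDKN2B (-0.97), PTCH1 (-10.76), EFNA5 (-13.18), EPHB6 (-10.87) and INPP5K (-4.39). The same held for DDIT4 (-4.62), CHAC1 (-3.67), MTHFD2 (-2.92), SLC7A11 (-1.45) and ASNS (-0.87). Also lower were RAB25 (-7.59), MAL2 (-2.79), TJP3 (-2.69), RFTN1 (-6.53), CLEC3A (-6.18), PCSK2 (-3.26), TK1 (-3.40), BAG3 (-1.31), ACSL1 (-1.68), SQOR (-9.74), NCKAP5 (-9.41), MECOM (-10.49), IRX3 (-11.58), CAPN13 (-11.07) and PDZRN3 (-12.10). Of these 43 genes 11 were run with each library left out, and 8 moved by over 0.585. Without SKBR3 knockdown 1 CA12 was at -7.84, FOXA1 at -10.96, IRX3 at -13.28 and EPHB6 at -13.11. IRX3 was at -10.67 without MCF7 knockdown 2 and -10.76 without SKBR3 control 1, and EPHB6 at -11.71 without MCF7 control 4. Without MCF7 knockdown 4 DUSP6 was at -4.07, EFNA5 at -11.88 and EPHB6 at -10.27. CAPN13 was at -12.76 without SKBR3 knockdown 2 and PDZRN3 at -10.45 without MCF7 knockdown 3. In 25 of the 99 genes a group held 3 counts or fewer, so the fitted value depends on the prior count. The 10 lists that differed had camera adjusted p of 1.81e-15 (interferon response), 5.60e-08 (antigen presentation), 4.28e-06 (luminal identity), 0.000152 (MAPK output), 0.000286 (basal epithelium), 0.000974 (ATF4), 0.00359 (androgen response), 0.00454 (NF-kB), 0.00818 (EMT) and 0.01002 (TGF-beta).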

How the results depend on the processing

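Counting protein-coding genes alone and leaving out both knockdown libraries numbered 4 were chosen only after seeing the data. SPDEF kept its fall past the threshold in both lines under every alternative run. Luminal identity passed in both lines under all of them too. The number of called genes moved with library totals alone (161 in MCF7, 161 of them at least 2-fold, 1928 for the difference, shared calls of 8 higher and 28 lower) and with DESeq2 (1046 in MCF7, 805 at least 2-fold, 100 and 136 shared). DESeq2 called 330 of the 341 MCF7 genes too. In the self-test for MCF7, DESeq2 recovered more changed genes than edgeR but made 42 false calls against 6. Which of these holds for its further calls in the real data was not tested. In SKBR3 the counts ran from 3498 with library totals alone to 5355 with DESeq2 before single libraries were left out, apart from 3335 and 3262 below. In the self-test edgeR recovered 2 of 67 genes changed 2-fold in MCF7 and 1 of 67 in SKBR3, so changes of that size were mostly missed in the simulated counts. These held 200 changed genes, and the adjusted threshold is stricter where fewer genes change. In the real SKBR3 comparison 4458 genes were called, of which 3907 changed at least 2-fold, so some smaller changes were called too. The self-test thus cannot tell how many 2-fold changes were missed in the SKBR3 data.

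With the replicate number as a block, edgeR called 142 genes in MCF7 (142 at least 2-fold), 3335 in SKBR3, 1835 for the difference and 6791 between the controls, with 12 and 24 shared calls higher and lower. Of the named genes 17 of 47 in MCF7, 4 of 88 in SKBR3, 2 of 23 in the difference and 1 of 27 between the controls were not called then. No clear pairing by number was seen: the correlation of deviations of same-numbered libraries ran from -0.05 to 0.17, and 3 of 8 pairs matched best with their own number. So few libraries cannot exclude a pairing. With only the 8 libraries of a comparison, the counts were 331, 3262 and 7072; this cannot be run for the difference.

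With 1 library left out, counts ran from 222 to 358 in MCF7 (220 to 348 at least 2-fold; 222 and 220 without MCF7 control 4), 3684 to 4982 in SKBR3 (3368 to 4225), 2407 to 3028 for the difference and 6789 to 8242 between the controls, and shared calls from 16 to 29 higher and 43 to 66 lower. SPDEF ran from -3.96 to -3.62 in MCF7 and -9.49 to -8.52 in SKBR3. WWTR1 and ERBB2 in MCF7 reached -0.38 and -0.352 at the other end, TEAD1 0.686, CCN1 0.890 and WWTR1 in the difference 0.654. CDH1 reached 2.08 in SKBR3 and 2.37 in the difference, TEAD4 in SKBR3 -0.184, and EMT between the controls an adjusted p of 0.993. The camera adjusted p of the lists ran as follows for MCF7, SKBR3 and the difference: HER2 amplicon 0.774 to 0.996, 0.308 to 0.697 and 0.682 to 0.987. For luminal identity it was 3.43e-06 to 0.000431, 4.01e-11 to 6.34e-10 and 2.20e-06 to 2.05e-05. For EMT it was 0.627 to 0.986, 0.00485 to 0.0335 and 0.00292 to 0.0261. For YAP/TEAD targets it was 0.725 to 0.986, 0.294 to 0.450 and 0.260 to 0.572.

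With fry, which does not compare a list with other genes, the HER2 amplicon (0.00715) and YAP/TEAD targets (0.000446) in SKBR3 and YAP/TEAD targets in the difference (0.00325) passed. In all, fry passed lists that camera did not call in every comparison: 1 in MCF7, 13 in SKBR3, 6 in the difference and 14 between the controls. With an estimated correlation EMT in SKBR3 did not pass (0.0767), and 6 of the 8 lists called in SKBR3, 1 in MCF7, 1 in the difference and 1 between the controls were lost. Lists not called otherwise passed in some runs. The Hippo and TEAD factors and the TGF-beta response did so in SKBR3 with the replicate block (0.0365 each). In the difference the Hippo and TEAD factors passed with library totals (0.0425), without MCF7 knockdown 4 (0.0372) and without both numbered 4 (0.0473). Fibroblast markers passed there with library totals (0.0259) and without MCF7 control 2 (0.0429), MCF7 knockdown 2 (0.0404) or 4 (0.0372) or SKBR3 knockdown 1 (0.0181), and immediate early genes without SKBR3 knockdown 2 (0.0458). Between the controls MAPK output passed with library totals (0.0307) and 8 libraries (0.0306), ERBB ligands and receptors with the block (0.0351) and 8 libraries (0.0376), ER stress with 8 libraries (0.0340) and without both numbered 4 (0.0437) and endothelial markers with 8 libraries (0.0261). In MCF7 the 5 genes checked for its label passed without MCF7 knockdown 2 (0.0257). The cause was not tested.

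Changes of sign were all in values that did not pass with the change, and their cause was not tested. WWTR1 in MCF7 turned to 0.0757 with RLE, 0.0752 with DESeq2, 0.00667 with the stricter filter, 0.0586 with 8 libraries, 0.0878 with protein-coding genes, and 0.162, 0.00706, 0.15, 0.34, 0.0109, 0.0111 and 6.72e-05 with a library left out, and in the difference to -0.0117. ERBB2 in MCF7 turned to 0.221, 0.0919 and 0.0637 with a library left out and 0.0584 without both numbered 4. TEAD1 turned to -0.128 between the controls with library totals and, without MCF7 knockdown 2, to -0.262 in MCF7, as did CCN1 (-0.425). Without SKBR3 knockdown 2 CDH1 turned to -0.489 in SKBR3 and -0.202 in the difference, and without SKBR3 control 4 TEAD4 turned to 0.0166 in SKBR3. Of lists, the direction changed for YAP/TEAD targets in MCF7 (adjusted p = 0.991 with library totals, 0.975, 0.956 and 0.973 with a library left out), the HER2 amplicon in MCF7 (0.774 and 0.961) and EMT between the controls (0.873, 0.968 and 0.967).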

Other observations

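Metabolic genes changed in both directions in the SKBR3 knockdown, as did genes in general. Of all 17225 genes tested, edgeR called 2062 higher and 2396 lower there. Camera called none of the lists given here in SKBR3, and counts near that background share do not set a list apart. Of 18 fatty acid synthesis genes 4 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.722): the desaturases FADS1 and FADS2, the lipid-binding protein FABP5 and the nuclear receptor PPARG rose, and fatty acid synthase FASN and its regulator SREBF1 were among those that fell. Of 24 cholesterol synthesis genes 5 rose, HMGCS1, LSS, DHCR7, SREBF2 and ACAT2, and 2 fell, DHCR24 and TM7SF2 (the same adjusted over the list alone, adjusted p = 0.321). Of 25 glycolysis and hypoxia genes 3 rose and 5 fell (3 and 6 adjusted over the list alone, adjusted p = 0.722), with hexokinase HK1 and pyruvate kinase PKM lower and TPI1 higher.

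Of 22 p53 targets in SKBR3, 2 rose, SESN1 and BTG2, and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.981), among them the cell cycle inhibitor CDKN1A. Of 24 S phase genes MCM2 and MCM3 rose and CDC6, UHRF1, FEN1 and TK1 fell (5 and 4 adjusted over the list alone, adjusted p = 0.722). Of 26 G2/M genes CCNB1, AURKB and CDC20 rose (2 adjusted over the list alone, adjusted p = 0.722). Of 19 ATF4 targets, a list called higher in MCF7, SESN2 rose and 6 fell in SKBR3 (2 and 6 adjusted over the list alone, adjusted p = 0.105). In MCF7 edgeR called 0 genes of the S phase list (0 at an unadjusted p under 0.05 and 0 by DESeq2). All members named here were chosen after their values were seen. The SKBR3 counts of these lists stand against 2062 higher and 2396 lower of all 17225 genes.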
